A study of Caenorhabditis elegans with 7 samples.

How the data were processed

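RNA of 7 samples of Caenorhabditis elegans at the first larval stage (L1) was measured, 4 from a strain whose ahr gene is described as nonfunctional (ahr-mutant) and 3 from the wild type. Per the labels, total RNA was reverse transcribed with a Cy3-labelled nucleotide and hybridized to a spotted array read in 1 colour. The titles of the mutant samples call them biological samples. Where separate cultures are not stated, p-values measure only the spread between these samples. Samples were grouped by the strain label. The labels number the mutant samples 56, 60, 62 and 54 and the wild-type samples 59, 61 and 63, so the strains alternate from 59 to 63. The replicate numbers used here follow the order of deposit and pair no samples.

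The deposited array files hold 1 linear intensity per spot for 23232 spots. Scanner, spot quantification and background treatment are not given in the sources used here. Each array had between 455 and 1031 blank spots and between 132 and 373 spots at 0. ahr-mutant replicate 3 also had 20 intensities below 0, and no other array had any. The signals were taken as already corrected for background on that ground, and the main fit has no further correction. The 1st percentile of the positive signals lay between 15336 and 21255 on the arrays, so a floor may remain and folds of dim spots may be understated. Blank, 0 and negative intensities were treated as missing. Spots blank on 1 of the 6 arrays other than ahr-mutant replicate 1 lay between the 94.9th and 97.2th percentile on other arrays, and spots at 0 between the 8.00th and 18.1th, so bright spots are among the missing values. The files hold no background columns, detection calls, scan dates or spot names.

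The authors also deposited a value table of 1290 rows. The authors' deposited values in it are a ratio of signals, by their fit to the array files, since the labels do not state how they were made. On the 1080 rows that matched a spot, each equals the deposited signal times 1 constant per array, divided by 1 constant per row. The median over the 7 arrays was 1 in all 538 rows that have a value for every array. The other 752 rows have no value for ahr-mutant replicate 1. The row numbers of the table are not those of the array files, so rows were matched by their values within 0.0001 on the log2 scale. The largest distance of a match was 2.53e-06 and the smallest distance to any other spot was 0.0537. After 27 rows that share a spot were set aside, 1053 spots had 1 table row, and 781 of these had 1 gene symbol. The annotation supplied with the table gives 1 gene for 961 rows and none for 329, and all 961 symbols matched the WBcel235 gene table. No coordinates are given because the build behind the array is not stated. Spots outside the table are unnamed here. How the authors chose the rows is not given in the sources used here, and the rows were compared on these same samples, so their direction is not independent evidence. All 538 rows with a value of ahr-mutant replicate 1 were higher in the other 3 mutants, and all 752 rows without one were lower. In 697 of the 752, the other 6 values imply that replicate 1 lay at or below the row median. Why these values are missing is not given in the sources used here.

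The rows of the file of ahr-mutant replicate 1 are in another order than those of the other arrays. Its rank correlations with them were between -0.0117 and 0.0354 as deposited, against 0.632 to 0.804 among the other 6. The order followed source plates of 384 wells with small shifts. Segments of at least 100 spots with a correlation of at least 0.7 to the mean of the other arrays were kept, less 10 spots at each end. Another 2 segments that met both limits, with 1535 spots, were set aside because 6 of the 29 positions known in them from exact table values lay elsewhere. This placed 19132 spots (82.4%) and left 4100 missing. Placing these segments as well, a setting added late, placed 20627 spots. Of 381 spots whose position in that file is known from an exact table value, 374 were found again by signal alone. In a test on simulated data all 21393 placed spots were put back correctly, and none of a shuffled array was placed.

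Intensities were taken to log2 and quantile normalized over each array's whole column, before replicate 1 was re-placed. A spot was tested with at least 2 values in each strain, which left 22498 spots. limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) compared the strains with no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are ahr-mutant against wild type, and errors of fold changes are standard errors. Single genes also had an exact two-sided permutation test over the 35 splits of 7 arrays, whose smallest p is 0.0286. Of 40 gene lists, 6 had at least 5 named genes measured on all arrays. They were tested with camera, with a preset correlation of 0.01, against the other named genes (691 genes in all). The design, the lists, the rule for named genes and most of the other settings were fixed before the data were examined. The rule names ahr-1 where measured, up to 12 rises and 12 falls past the threshold with non-overlapping groups, then the genes with the smallest unadjusted p until there are 20, and up to 4 members with the smallest p in each list that is described.

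Choices made after the data were seen bear on the count of called spots. The design held normexp with offset 50 for signals not already corrected for background. Leaving out normexp was decided from the values. With it at offset 50, limma called 0 spots, with a smallest adjusted p of 0.0831. The first run of the fit normalized after replicate 1 had been re-placed and called 0 spots, with a smallest adjusted p of 0.0502. Normalizing before that step uses every spot of each array, was then taken as the main order, and called 2 spots at an adjusted p of 0.0491. In all, 23 settings of the array fit were run, 9 of them added after the data were seen, and 15 of the 23 called none. Among the added ones, position on the slide was adjusted by subtracting the median of each of 48 blocks of 22 by 22 spots, or the local median of an array's deviations from the spot means in a window of 11 by 11 spots, with windows of 7 and 15 spots as well.

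On simulated data with 200 changed spots among the 22498, limma recovered 0% of spots changed by 1 on the log2 scale, 32.0% of those changed by 2, 74.0% by 3 and 92.0% by 4. The simulated spots varied independently of each other, without drift over the slide, so these shares may not hold for the real arrays. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9, and the matching used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.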

Results

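The series compared L1 larvae of an ahr mutant with wild-type larvae. The ahr gene of the worm encodes the counterpart of the vertebrate aryl hydrocarbon receptor, a ligand-activated transcription factor. Whole larvae were measured, 4 ahr-mutant and 3 wild-type samples, on 1 array each. Between 21942 and 22593 spots of an array had a positive signal, and median signals lay between 52277 and 90919 intensity units. The ahr-1 transcript and the list of its bHLH-PAS partners were not analysed here, because no named spot belongs to them.

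Genes changed between the strains were sought over 22498 spots. The neurotransmitter transporter family gene snf-5 was 12.7-fold lower in the mutants, at 15.39 ± 0.38 on the log2 scale (SD, n = 4) against 19.06 ± 0.51 in the wild type (SD, n = 3). Its log2 difference was -3.67 ± 0.38 (SE), with a limma adjusted p of 0.0491 and an exact permutation p of 0.0286, the smallest possible. As snf-5 was chosen for its small p, the permutation p adds no separate evidence. cyp-25A1, at a limma adjusted p of 0.438, had the same permutation p. The other spot past the threshold has no gene name here and was 10.3-fold higher in the mutants (log2 difference 3.36 ± 0.36, SE; adjusted p = 0.0491). These 2 calls were marginal. Quantile normalization after re-placing replicate 1, the order that was run first, gave 0 calls with a smallest adjusted p of 0.0502, normexp gave 0 calls, and leaving out any 1 of the 7 arrays gave 0 calls.

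The difference between the strains also varied with position on the slide. Over spots outside the deposited table, the median log2 difference ran from -0.46 in the first of 12 slide rows of blocks to 0.50 in the last, a span of 0.96. Differences between single arrays of the same strain, which average over fewer arrays, had spans of 0.57 to 1.99, and 5 of these 9 pairs reached that of the strains. Among the mutant arrays, replicate 3 changed most, with a median deviation from the spot means of -0.91 in slide row 1 and 0.66 in slide row 12. Replicate 4 changed the other way, from 0.15 to -0.18. The snf-5 spot lies in slide row 1 and the unnamed spot in slide row 10. With the local position adjustment, snf-5 was 6.46-fold lower (adjusted p = 0.0698) and no longer passed, while the unnamed spot was 7.67-fold higher (adjusted p = 0.0161). The adjusted fit called 3 spots. Besides the unnamed one above, these were another unnamed spot, 7.97-fold lower in the mutants (adjusted p = 0.0161), and rabs-5, which encodes a relative of the endosomal protein rabenosyn-5. rabs-5 was named after its values were seen. It was 10.7-fold lower with the adjustment (log2 difference -3.43 ± 0.36, SE; adjusted p = 0.0171) and 7.56-fold lower without it (adjusted p = 0.216). With block medians subtracted rabs-5 was 11.8-fold lower and did not pass (limma adjusted p = 0.0853). rabs-5 and the unnamed spot that was lower both lie in slide row 12, where spots outside the table had a median difference of 0.50.

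A further 19 named genes had the smallest unadjusted p-values and did not pass, with adjusted p between 0.0827 and 0.216. With snf-5 they make 20 genes, of which 16 had higher and 4 had lower means in the mutants. Among those with lower means, Y59E9AL.5 was 6.61-fold lower, spl-2, which encodes a sphingosine-1-phosphate lyase, was 6.36-fold lower, and lgmn-1, related to the protease legumain, was 3.76-fold lower. Chemosensory receptor genes stood among those with higher means, namely srd-31 with a log2 difference of 3.32, sre-44 at 8.25-fold, sru-9 at 5.33-fold (n = 3 mutants) and srx-77 at 4.34-fold. The remaining genes with higher means were B0205.5 (7.02-fold), M01B2.8 (6.20-fold), Y38H8A.4 (5.22-fold), T24G10.2 (5.16-fold), T23G11.1 (4.99-fold), the RNA polymerase subunit gene rpb-11 (4.65-fold), the transporter gene slc-17.9 (4.54-fold), the F-box gene fbxa-130 (4.12-fold), mfsd-12 (3.95-fold), taap-1 (3.91-fold), ZC155.2 (3.87-fold) and 2L52.1 (3.48-fold). All 16 lie in slide rows 10 to 12, and the 4 with lower means in slide rows 1 to 5. All 20 kept their direction with the local position adjustment, where the 16 were between 2.33-fold and 7.72-fold higher and adjusted p lay between 0.0659 and 0.339. The folds that fell by more than 1.5 times among the 16 were those of sre-44 (to 4.71-fold), B0205.5 (to 4.64-fold), Y38H8A.4 (to 3.29-fold), T23G11.1 (to 3.01-fold), slc-17.9 (to 3.00-fold) and srx-77 (to 2.86-fold).

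**Figure D1:**
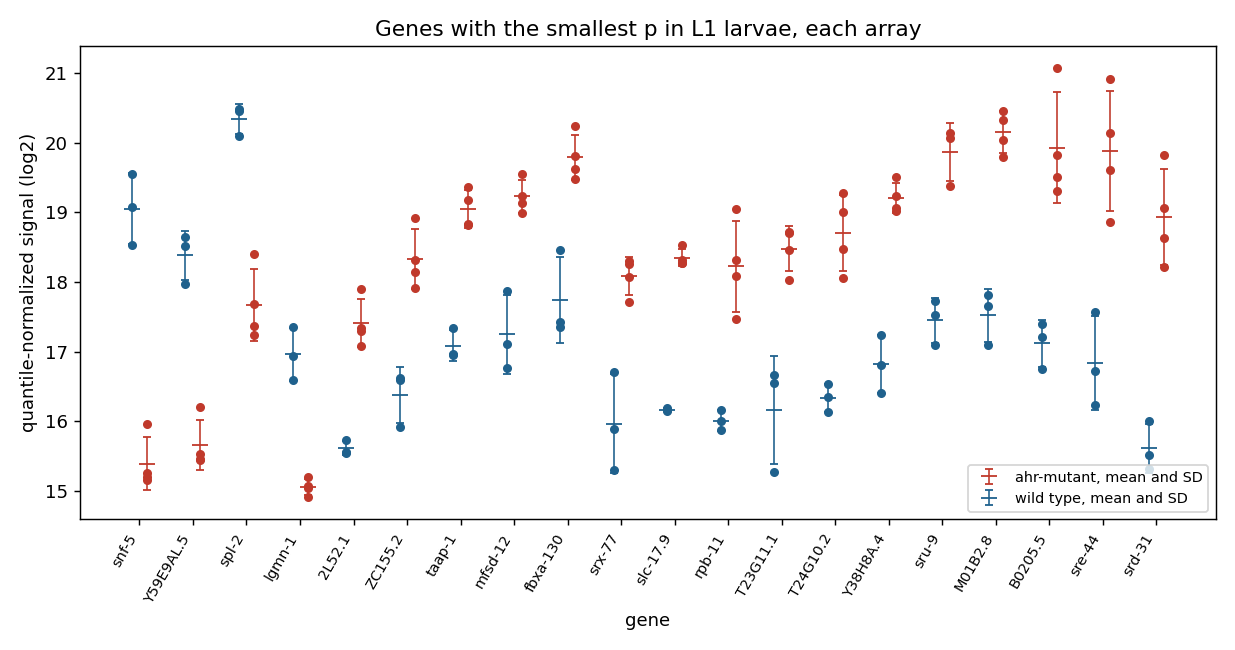
Quantile-normalized log2 signal (vertical axis) of the 20 genes with the smallest p (horizontal axis), 1 point per array, red for ahr-mutant and blue for wild type, with bars for mean and SD. Only snf-5, with means of 15.39 and 19.06, passed the adjusted threshold.

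At an unadjusted p under 0.05, 1715 spots (7.62%) differed, against 1125 expected by chance, 914 of them higher and 801 lower in the mutants. Median scaling in place of quantile normalization moved the share of higher spots from 53.3% to 42.3%. The deposited table holds 1053 matched spots, 646 lower and 407 higher in the mutants by its own values, taken over the 3 mutants other than replicate 1. The lower ones are those without a value of replicate 1 and the higher ones those with it. Of the 1053, 668 reached an unadjusted p under 0.05 in that direction. Of the spots outside that list, 4.88% did so in either direction. The table's directions come from these same samples, so the 668 are no independent evidence. Setting the table apart may also lower the share outside it, so the 4.88% is not a background rate. In slide rows 1 to 4 the table had 394 lower and 10 higher spots, and in slide rows 9 to 12 it had 19 lower and 330 higher. With the local position adjustment 1009 of the 1053 kept their direction, 413 reached an unadjusted p under 0.05, and the median absolute log2 difference went from 0.94 to 0.55.

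**Figure D2:**
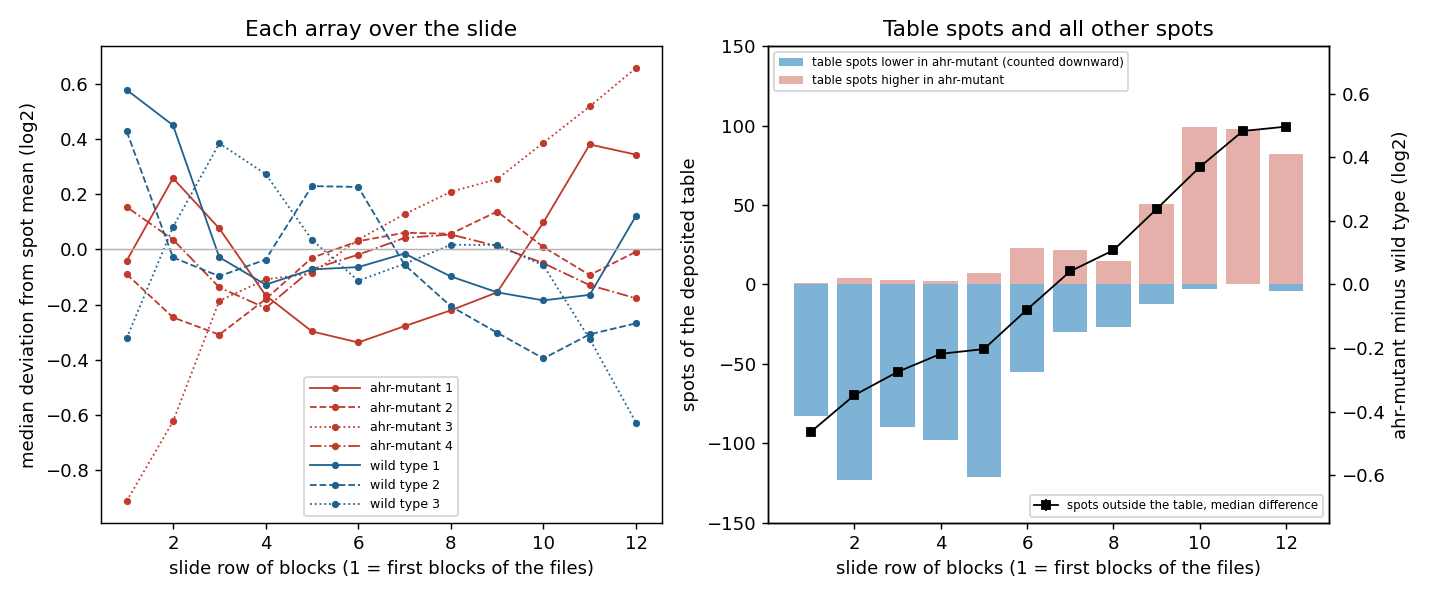
Left, the median deviation of each array from the spot means (log2) in each of 12 slide rows of blocks, over spots outside the table, red for ahr-mutant and blue for wild type. Right, deposited table spots per slide row, higher in the mutants as bars upward and lower as bars downward, with the median difference of all other spots (squares, bootstrap SE, right axis), which runs from -0.46 to 0.50 as the table spots turn from lower to higher.

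Gene lists were compared to ask whether functional groups moved together. None of the 6 lists tested was shifted against the other named genes (camera, lowest adjusted p = 0.549; adjusted p = 0.932 for every list with an estimated correlation). Medians, means and p-values of lists are over the members measured on all arrays, 47 of 57 chemosensory receptors, 18 of 21 innate immunity effectors, 15 of 16 nuclear hormone receptors, 6 of 8 cuticle collagens, 6 of 7 UDP-glucuronosyltransferases and 6 of 6 cytochrome P450s. All members, and the genes they were tested against, come from the deposited table, which was compared on these samples. The camera test therefore shows only whether a list differed from the other table genes. Whether a list moved against all genes on the array cannot be told from it. Counts adjusted over the list alone are not independent evidence either. No member of the 6 lists passed over all spots tested.

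Chemosensory receptors, the family of odorant receptor genes, had 57 named members, 37 with lower and 20 with higher means in the mutants. Adjusted over the list alone, 18 lower and 15 higher ones passed. The list's median log2 difference was -0.66 and its mean -0.15, against a median of -0.52 over the 691 named genes (adjusted p = 0.915). Its members had a median slide row of 5. With the local position adjustment the median was -0.28 and the mean 0.008, and the direction of the camera test turned from downward to upward (adjusted p = 0.808).

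Innate immunity effectors, mostly C-type lectins, had 21 named members, 15 with lower and 6 with higher means. Adjusted over the list alone, 10 lower and 5 higher ones passed. The lectin genes clec-137 (4.37-fold lower), clec-104 (4.24-fold lower), clec-244 (3.17-fold lower) and clec-126 (3.69-fold higher, 2.22-fold with the local position adjustment) had the smallest p-values, with adjusted p of 0.321 or more. The list's median was -0.96 (camera adjusted p = 0.549), and -0.68 with the local position adjustment (adjusted p = 0.199).

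Of 6 cytochrome P450 genes 3 had higher and 3 lower means, and adjusted over the list alone 2 higher and 3 lower ones passed. cyp-34A5 was 3.33-fold and cyp-25A1 2.77-fold higher, while cyp-13A1 was 2.52-fold and cyp-14A1 2.23-fold lower, and none passed over all spots. With the local position adjustment the first 2 were 2.50-fold and 2.02-fold higher and the last 2 were 2.25-fold and 1.56-fold lower. The median of the list was -0.17, its mean 0.06 and the direction of its test upward (adjusted p = 0.891). With the local position adjustment its median was 0.09 (camera adjusted p = 0.808). Of 7 UDP-glucuronosyltransferase genes, whose enzymes conjugate lipophilic compounds, 5 had lower and 2 higher means, and 0 passed over the list alone. ugt-8 was 2.27-fold, ugt-54 2.23-fold, ugt-63 2.01-fold and ugt-2 1.89-fold lower, and with the local position adjustment these were between 1.29-fold (ugt-63) and 1.41-fold (ugt-54) lower. The glutathione S-transferase genes gst-35 and gst-12 were 1.49-fold and 1.46-fold lower, too few for a list test, and 1.09-fold and 1.48-fold lower with the local position adjustment. The P450 members had a median slide row of 7 and the UDP-glucuronosyltransferase members of 4.

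Nuclear hormone receptors, a family of transcription factors, had 16 named members, 9 with higher and 7 with lower means, and 1 higher one passed over the list alone. nhr-109 was 4.86-fold and nhr-220 2.48-fold higher, while nhr-210 was 2.87-fold and nhr-217 2.71-fold lower. With the local position adjustment nhr-109 was 3.89-fold and nhr-220 2.59-fold higher, and nhr-210 was 1.72-fold and nhr-217 2.37-fold lower with overlapping strains. The median of the list was 0.56 and went to 0.04 with the local position adjustment (median slide row 7.5), with 8 members higher and 8 lower. Cuticle collagens, a hypodermal marker group, had 8 named members, 5 with lower and 3 with higher means. Adjusted over the list alone 2 lower and 3 higher ones passed. col-105 was 3.39-fold and dpy-14 3.10-fold lower, and col-45 was 3.04-fold and col-154 1.99-fold higher (n = 3 mutants for dpy-14 and col-45; median slide row 4.5). With the local position adjustment these were 2.06-fold and 1.75-fold lower and 2.48-fold and 1.31-fold higher, and the strains then overlapped for col-105 and col-154. The list then had 4 higher and 4 lower members, its median went from -0.72 to -0.12, and the direction of its test turned from downward to upward (adjusted p = 0.891 before and 0.808 after).

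Markers of tissues and other stages were sparse. GABA neuron, pan-neuronal, muscle and intestine markers and the vitellogenins had no named member. Among touch receptor neuron markers, the tubulin gene mec-7 was 3.07-fold and the channel gene mec-4 2.30-fold higher, and alr-1 was 1.44-fold lower. These 3 lie in slide rows 11, 12 and 6. With the local position adjustment mec-4 was 1.60-fold higher and alr-1 1.22-fold lower. Sperm proteins had nspd-7 at 6.16-fold, nspd-10 at 3.25-fold and msp-78 at 2.10-fold higher and ssp-19 at 1.68-fold lower. With the local position adjustment these were 4.32-fold, 2.45-fold and 1.52-fold higher and 1.20-fold lower (slide rows 7, 8, 9 and 2). The cilium genes dyf-4 and bbs-5, in slide rows 2 and 4, were 3.31-fold and 2.59-fold lower. With the local position adjustment they were 2.02-fold and 2.47-fold lower. Table spots were mostly lower in slide rows 2 and 4 and mostly higher in slide rows 11 and 12, so these directions are also those of the position. None of the marker genes passed over all spots (lowest limma adjusted p = 0.321, for mec-7, which was 2.28-fold higher with the local position adjustment).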

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

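All tests of slide position and of row order below were chosen after the result was seen, and the counts over other splits of the samples were planned before they were computed.

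Of 41 sets of 4 mutant values examined, 5 had a sample far from the others, where about 1 in 20 is expected by chance. ahr-mutant replicate 1 stood above the other mutants for snf-5 (15.96 on the log2 scale), Y59E9AL.5 (16.197) and slc-17.9 (18.53). ahr-mutant replicate 3 stood below the others for ugt-8 (15.99), and ahr-mutant replicate 2 for ugt-63 (17.75).

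The table spots that were lower in the mutants lay in the first slide rows and those that were higher in the last. The direction of 92.2% of table spots was that of the spots outside the table in the same block, against at most 57.8% in 10000 permutations of the directions, so array signals that drift over the slide may have shaped the table. A strain difference in the table's genes alone would leave the other spots level, but their slide-row medians spanned 0.96 on the log2 scale. Source plates explained 0.0278 times the share of variance that slide rows explained. In the printing order used here each plate is spread evenly over all 12 slide rows, so this comparison could not come out otherwise. It decides nothing about related oligos printed together, and whether related oligos share well positions was not tested. Whether the drift belongs to the strain could not be told: 6 of the 35 splits of the 7 arrays, the real one among them, had a span as large. The highest other split had 1.21. The mutant arrays did not share 1 trend. From slide row 1 to 12 the median deviation from the spot means went from -0.91 to 0.66 in ahr-mutant replicate 3. It went from -0.04 to 0.34 in replicate 1, -0.09 to -0.008 in replicate 2 and 0.15 to -0.18 in replicate 4. The wild-type arrays went from 0.58 to 0.12, 0.43 to -0.27 and -0.32 to -0.63. Of 9 pairs of single arrays of the same strain, which average over fewer arrays, 5 had a span as large, between 0.57 and 1.99 over all 9. A strain difference in single genes on top of the drift stays open.

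ahr-mutant replicate 1 had no correlation with the other arrays as deposited. For the spots that could be placed, its rows are in another order. All 424 matched table rows with a value of replicate 1 were found in its file by exact value. Of the 381 with a single position there, 374 were found again by signal alone. A failed hybridization is argued against by the 381 positions known from exact table values, which no alignment chose. There its median rank correlation with the other arrays was 0.873 (95% bootstrap interval 0.847 to 0.891), against 0.828 to 0.934 among the other 6 arrays. These are table spots, which were compared on the same samples. Which RNA was hybridized was not tested.

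In the counts of splits below, the real split is among those counted. Chance was not excluded for the 2 spots past the threshold: 2 of the 35 splits of the 7 arrays gave as many, and the highest other split gave 4. Nor was it excluded for the 1715 spots at an unadjusted p under 0.05, which 2 of 35 splits reached, the highest other with 2092. For gene lists the real count of 0 was reached by 35 of 35 splits by construction, the highest other giving 2. With the local position adjustment, only the real split of the 35 reached 3 spots past the threshold, and the highest other gave 2. This is the lowest share that 35 splits can give, for 1 of several counts examined, in a fit added after the data were seen. Chance was therefore not excluded for this count either. The 1585 spots of that fit at an unadjusted p under 0.05 were reached by 3 of 35 splits, the highest other with 1709.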

How the results depend on the processing

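Position adjustments, the other treatments of replicate 1 and the restriction to complete spots were added after the data were seen. The run with normexp at offset 50 was added then too, but the design had held that correction for signals not already corrected. The other settings were planned. The 2 called spots became 0 with normexp at offset 16 or 50, median scaling, cyclic loess, eBayes with trend and robust fitting, only the arrays numbered 59 to 63, replicate 1 in its deposited row order and normalization after re-placing it. Leaving out each array in turn gave between 0 and 0 spots. The count was 11 at an adjusted p under 0.10, and 2 with array weights or with complete spots alone, the same spots in both. It was also 2 with the set-aside segments of replicate 1 placed as well, snf-5 among them. With block medians subtracted it was 2 as well, but these were both unnamed spots, and snf-5, at 8.06-fold lower, no longer passed (adjusted p = 0.0853). The local position adjustment called 3 spots, and the 3 were shared by all 3 window sizes. The cause of the losses was not tested. The left-out fits also have fewer samples. Over its 1053 matched spots, selected already, the authors' value table gave 886 past the threshold, and 373 higher spots at an unadjusted p under 0.05, with no value of replicate 1 in most rows. Its list test gave 1 shifted list (chemosensory receptors), but could use only the 305 genes with a value of replicate 1, 20 receptors among them. These rows are all higher in the mutants and leave out the lower receptors, so this is no evidence of a shift. Replicate 1 in its deposited order gave 389 higher spots at an unadjusted p under 0.05 in place of 914. Leaving out arrays gave between 594 (without wild type replicate 2) and 1099 higher ones. Table spots in their deposited direction at an unadjusted p under 0.05 went from 668 to 351 with block medians subtracted, 413, 400 and 416 with local windows of 11, 7 and 15 spots, and 316 with the deposited order of replicate 1. fry gave 1 shifted list in place of 0, the innate immunity effectors (fry adjusted p = 0.0362). But fry compares members with no change, while the named genes of the table had a median log2 difference of -0.52. Of 917 values of 40 named genes, 859 kept their direction and side of the threshold, 39 passed only with the authors' table, and 19, all of snf-5, no longer passed; none changed direction. snf-5 stayed between 6.38-fold and 17.97-fold lower in the array fits. Not run were a filter against background and a slide or scan block, for which the files used here hold no columns, and repeated spots or probes of a gene, which are not marked; no filter and no background correction are the reported setting. No paired analysis was possible because the label numbers pair no samples and the replicate numbers used here follow the order of deposit. Signal over background is unknown, so its limit on dim spots was not assessed, nor was that of blank bright spots.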

Other observations

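Several small gene groups had members in the deposited table that have not been described above. All 3 ABC transporter genes had lower means in the mutants, with pmp-3 at 4.06-fold, mrp-6 at 2.67-fold and pgp-7 at 1.54-fold lower, and 2.17-fold, 1.92-fold and 1.94-fold with the local position adjustment. The globin genes glb-32 and glb-28, in slide rows 2 and 3, were 2.43-fold and 2.12-fold lower, and 2.03-fold and 1.65-fold with the adjustment. The hedgehog-related gene grd-3 was 4.46-fold lower, and 2.46-fold with the adjustment, while grl-9 was 1.66-fold lower and turned to 1.09-fold higher with it. The 4 ribosomal protein genes were divided. rpl-24 was 3.39-fold and rpl-4 2.99-fold lower, both in slide row 1, and 1.85-fold and 1.53-fold with the adjustment, rps-17 was 1.31-fold lower, and rpl-35A, in slide row 11, was 1.87-fold higher. None of these passed over all spots tested.

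Within the 961 named rows of the deposited table, 551 were lower and 410 higher in the mutants. Among 7 lists with at least 5 rows, none departed from that division by Fisher's exact test (lowest adjusted p = 0.760).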
